A study of Mus musculus with 22 samples.

How the data were processed

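RNA was measured in 10 libraries of mouse bone marrow-derived macrophages (control, LPS, LA, LPS+LA and LPS+HCl, 2 each) and open chromatin in 12 ATAC-seq samples (control, LPS, LA and LPS+LA, 3 each). Samples were placed in groups by their labels alone. The gene lists, tests, thresholds, alternatives and the rule for named genes were chosen before the data were examined. Total-count scaling, fits without both libraries with brain transcripts, strata of gene length, distances from gene bounds, sites defined on only 2 LPS samples and log CPM differences were added after seeing the data.

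For RNA the authors deposited a table of 16059 genes with an expected count, an FPKM value and a TPM value per gene and library. Per the submitters' processing notes, HISAT and Bowtie2 were used with GRCm38.p6, and the tool that made the expected counts is not given in the sources used here. Expected counts are estimates that divide reads between similar genes, so 6.07% of the deposited expected counts were not whole, and all were rounded to whole numbers. The deposited FPKM and TPM values were not used for tests, because they no longer hold the depth of each library. Whether counting used strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be separated, and counts of near-identical paralogs such as Hspa1a and Hspa1b are uncertain. Of the gene IDs, 15959 matched a RefSeq gene table of GRCm38.p6, which gave symbols, chromosomes and gene bounds, and 23 symbols turned into dates by a spreadsheet were read through their IDs. The 13 mitochondrial transcripts listed as a sign of RNA quality had 0 members in the table.

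For ATAC-seq the authors deposited a list of peaks per sample with a score per peak, called per sample with MACS2, per the file headers. The submitters' processing notes give MACS2 2.0.10 and mm10 (GRCm38) and also name BWA 0.5.9 and Picard. The deposited score is the authors' own value, and it served only to rank or filter peaks. Peak lists hold no read counts, so a site without a peak may still hold reads below the caller's threshold, and a deeper sample can have more peaks. How reads were shifted for the transposase is not given in the sources used here. The sequencing lane was read from the file headers.

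Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12213 of 16059. Library sizes were scaled by TMM. A model with 1 term per group was fitted to all 10 libraries with edgeR 4.0.16 (glmQLFit, robust), and contrasts were tested by edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The interaction was the LA effect with LPS minus the LA effect without it. TMM assumes that most genes keep their share of the RNA. Here the TMM factors ran from 0.759 in LPS to 1.27 in control, so total-count scaling, with each factor at 1, was run beside it. Library totals ran from 18668666 to 20219895 counts. Where a group had no count, a floor of 3 counts over the group gave a bound, and with 1 to 3 counts a ratio of counts was given with its exact 95% interval.

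Genes were named by a rule: in each contrast the 5 largest rises and 5 largest falls among called genes with at least 10 CPM in a group and no overlap between groups, up to 4 members of each described list with the smallest adjusted p, and a fixed panel of inflammatory and metabolic genes. Arg1, a panel gene, was too low to be tested, and some genes that the rule names are not reported here. Outside the rule, Tnfsf9 was named with the cytokines after its values were seen. Gene lists (34 lists, 609 genes, 563 of them in the table) were tested by camera in limma 3.58.1 with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. Comparisons that share LPS libraries were set against 20 simulations of unchanged groups.

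ATAC peaks of all samples were merged in Python at an overlap of at least 1 bp. A site was counted as gained or lost where it had a peak in each sample of one group and in none of the other. Numbers of peaks were compared by two-sided exact permutation within the state of the other factor. Peak sets were compared by the Jaccard index, from bedtools 2.31.1, over all 15400 partitions of the samples. Sites were set beside genes within 50 kb of the gene bounds for the 12165 tested genes with a position, by two-sided Fisher's exact test. The planned distance was from the gene start, but the gene table gives no strand, so gene bounds were used. Distances of 10 kb and 100 kb gave odds ratios of 2.30 and 2.15 where 50 kb gave 2.09.

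The steps were tested on simulated data. For LPS+LA against LPS, with 12213 genes and 50 changed per fold size, the edgeR step recovered 50% at log2 0.5, 68% at 1, 86% at 2 and 90% at 3, with 5.16% false calls among all calls. In the camera step a set of 20 genes shifted by log2 0.5 was found and 0 of 20 unchanged sets were called. For LPS against control the ATAC step, on 20000 sites, recovered 96.6% of 500 gained sites. Python 3.11.15, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and DESeq2 1.42.0 were also used.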

Results

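Bone marrow-derived macrophages, phagocytes grown from C57/BL6 mouse marrow for 7 days in medium with L929 cell supernatant, were stimulated for 3 h with lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor signalling. LPS was given at 100 ng/ml, alone, with L-(+)-lactic acid (LA) or with hydrochloric acid (HCl). The LA dose was 10 mM with LPS, and the dose of LA alone is not stated in the labels. For the HCl group, which carries acidity without added lactate, the labels give a pH of 6.5 as an example, and the pH with LA is not stated. Steady-state RNA was counted by RNA-seq in 5 groups of 2 libraries: control, LPS, LA, LPS+LA and LPS+HCl. Open chromatin was mapped by ATAC-seq, in which a transposase cuts accessible DNA, in 4 groups of 3 samples: control, LPS, LA and LPS+LA. The 10 RNA libraries held 18668666 to 20219895 counts each, and the 12 ATAC samples held 76680 to 100667 called peaks each. Nothing in the labels states that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. RNA levels are CPM, counts relative to TMM-scaled library size, as mean ± SD of n = 2 libraries, and log2 values are fold changes from edgeR.

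The RNA libraries separated by treatment, with 67.0% of the variance of all genes on the first principal component and 11.7% on the second. Replicate libraries correlated at 0.982 to 0.992 across genes and differed by more than counting error in each group. Macrophage identity genes summed to 19965 CPM in control, 21924 in LA, 24956 in LPS, 23070.5 in LPS+HCl and 23248 in LPS+LA, while markers of T, B, natural killer, erythroid and mast cells each summed to at most 8.14 CPM. Transcripts typical of brain stood apart in 2 libraries. Neuron markers summed to 66.6 CPM in control replicate 1 and 93.6 CPM in LPS+HCl replicate 2, against at most 16.0 CPM in any other library.

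The first comparison asked how LPS alone changed the resting macrophage. LPS raised inflammatory genes, some of them from near silence. Tnf (NCBI Gene 21926, chromosome 17, 35199367 to 35202007), which encodes a central inflammatory cytokine, rose from 29.4 ± 0.0886 to 10969.7 ± 523 CPM (log2 8.54, SE 0.28). Il1b (NCBI Gene 16176, chromosome 2, 129364569 to 129371164), the interleukin that drives fever and neutrophil influx, rose from 0.644 ± 0.167 to 3793 ± 61.5 CPM (log2 12.51). Il6 (NCBI Gene 16193, chromosome 5, 30013114 to 30019975), which encodes a cytokine of the acute phase response, had no count in either control library and reached 828 ± 38.3 CPM, at least 13709-fold higher against a floor of 3 counts over the control group. Nos2 (NCBI Gene 18126, chromosome 11, 78920787 to 78960226), the inducible nitric oxide synthase, had 1 count over both control libraries and reached 1884 ± 73.6 CPM, a count ratio of 93585 with a 95% counting interval of 16796 to 3.70e+06. The largest adjusted p of these 4 genes was 5.82e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

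Other genes with large fitted rises encode secreted signalling proteins. With 0 to 2 control counts these fitted values are no bound, so the order of such genes is not fixed. Il1a, an alarmin cytokine, reached 2013 ± 15.1 CPM from 2 control counts, a count ratio of 49993 (95% counting interval 13839 to 412819). Il12b, the shared subunit of interleukins that polarise T cells, reached 735 ± 42.5 CPM from 1 control count, a count ratio of 36541 (6558 to 1.44e+06). Csf2, the granulocyte-macrophage growth factor, reached 46.2 ± 4.08 CPM and Ifnb1, the type I interferon beta gene, 23.8 ± 2.32 CPM, both from no control count. These were at least 766-fold and 394-fold higher. Such floors and counting intervals cover counting error only. The control counts of Nos2 and Il1a lay in control replicate 2 and that of Il12b in control replicate 1, and without that library the fitted log2 values went from 16.12, 15.40 and 14.77 to 18.16, 18.25 and 16.80. Cxcl10 (11.7 to 14439 CPM, log2 10.26), a chemokine for T cells, Ptgs2 (0.966 to 2963 CPM, log2 11.57), the inducible cyclooxygenase, and Acod1 (15.9 to 12191 CPM, log2 9.58), which makes itaconate, rose too. Ccl2 (59.5 to 2425 CPM, log2 5.35), the monocyte chemokine, and Il10 (0.482 to 17.3 CPM, log2 5.14), an anti-inflammatory cytokine, also rose. The greatest falls were those of Fam78a (32.4 to 0.198 CPM, log2 −7.32), Zfp395 (50.1 to 0.525 CPM, log2 −6.56), Cd300lb (149 to 2.1 CPM, log2 −6.15), an activating myeloid receptor, Lyl1 (110.2 to 1.7 CPM, log2 −6.01), a haematopoietic transcription factor, and Sox4 (10.4 to 0.165 CPM, log2 −5.93). Vegfa (36.5 to 7.59 CPM, log2 −2.27), the angiogenic growth factor, Txnip (373 to 153 CPM, log2 −1.29), an inhibitor of glucose uptake, and Nr4a1 (3.38 to 1.76 CPM, log2 −0.93), an early-response nuclear receptor, fell. Without LPS replicate 1 or 2 the log2 of Fam78a was −6.59 or −8.84 and that of Sox4 −5.26 or −7.19, and without control replicate 2 that of Il10 was 5.90.

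Whole families of immune genes rose together with LPS. All 19 tested inflammatory cytokines rose (19 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 1.81e-11, adjusted p = 0.111 with an estimated correlation), among them Csf1 (18.4 to 1244 CPM, log2 6.08) and Tnfsf15 (0.423 to 362 CPM, log2 9.72). All 16 chemokines rose (16 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 7.67e-10, adjusted p = 0.0466 with an estimated correlation), with Cxcl9 (0.161 to 504 CPM, log2 11.56) and Ccl9 (666 to 4123 CPM, log2 2.63) among them. The 33 type I interferon response genes also rose without exception (33 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 8.3e-17, adjusted p = 0.258 with an estimated correlation). They included Ifit2 (26.7 to 3659.8 CPM, log2 7.10), which blocks viral translation, Ifih1 (41 to 1426 CPM, log2 5.12), a sensor of viral RNA, and Usp18 (16.4 to 673 CPM, log2 5.36), which damps interferon receptor signalling. All 28 genes of NF-kB signalling and its feedback rose (28 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 5.31e-17, adjusted p = 0.0318 with an estimated correlation), including Socs3 (6.96 to 2405 CPM, log2 8.43) and Tnfaip3 (25.3 to 2423 CPM, log2 6.58), both inhibitors of inflammatory signalling, and Nfkbiz (11.4 to 1644 CPM, log2 7.17). Of 21 antimicrobial and prostanoid effectors, 18 rose and 1 fell (18 higher and 1 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 1.16e-08, adjusted p = 0.0318 with an estimated correlation), with Sod2 (56.8 to 798 CPM, log2 3.81), a mitochondrial antioxidant enzyme, and Saa3 (1.23 to 281 CPM, log2 7.83) among the risers. Of 20 genes of antigen presentation and costimulation, 18 rose and none fell, while with total-count scaling 15 rose and 2 fell (18 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 2.87e-08, adjusted p = 0.126 with an estimated correlation). Examples were Icam1 (96 to 4388 CPM, log2 5.51), an adhesion molecule, and Cd40 (3.44 to 869 CPM, log2 7.98), a costimulatory receptor.

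Proliferation genes moved the other way, and metabolic genes split by scaling. Of 27 cell cycle genes, 24 fell and none rose (0 higher and 24 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 6.51e-07, adjusted p = 0.218 with an estimated correlation). Ccnd1 (444 to 106 CPM, log2 −2.07), the cyclin of early G1 phase, and Cdc6 (26.9 to 1.31 CPM, log2 −4.35), which licenses replication origins, were among them. Of 27 glycolysis and hypoxia genes, 19 rose and 5 fell, a direction that flipped to 10 higher and 15 lower with total-count scaling (19 higher and 5 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.0105, adjusted p = 0.545 with an estimated correlation). Pfkfb3 (21.2 to 241 CPM, log2 3.51), an activator of glycolysis, and Hk2 (39.7 to 204 CPM, log2 2.36), a hexokinase, were higher under both scalings. Of 28 oxidative phosphorylation genes, 18 rose and none fell, against 1 higher and 26 lower with total-count scaling (18 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.00224, adjusted p = 0.372 with an estimated correlation). Slc16a3, a lactate exporter, and Ldha, lactate dehydrogenase, had log2 values of 0.56 and 0.32, and these turned to −0.15 and −0.40 with total-count scaling.

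In all, edgeR's quasi-likelihood test called 7914 of 12213 genes between LPS and control, 3963 higher and 3951 lower, and 1792 and 1968 of these changed by log2 of at least 1. With total-count scaling, which shifted the median of all genes by −0.72 log2, the calls were 1761 higher and 8289 lower. Myc, a proliferation factor, fell (log2 −0.37), but without control replicate 2 it did not pass edgeR's quasi-likelihood test (log2 −0.30, Benjamini-Hochberg adjusted p = 0.0757, range over its alternatives 6.18e-08 to 0.0757).

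**Figure D1:**
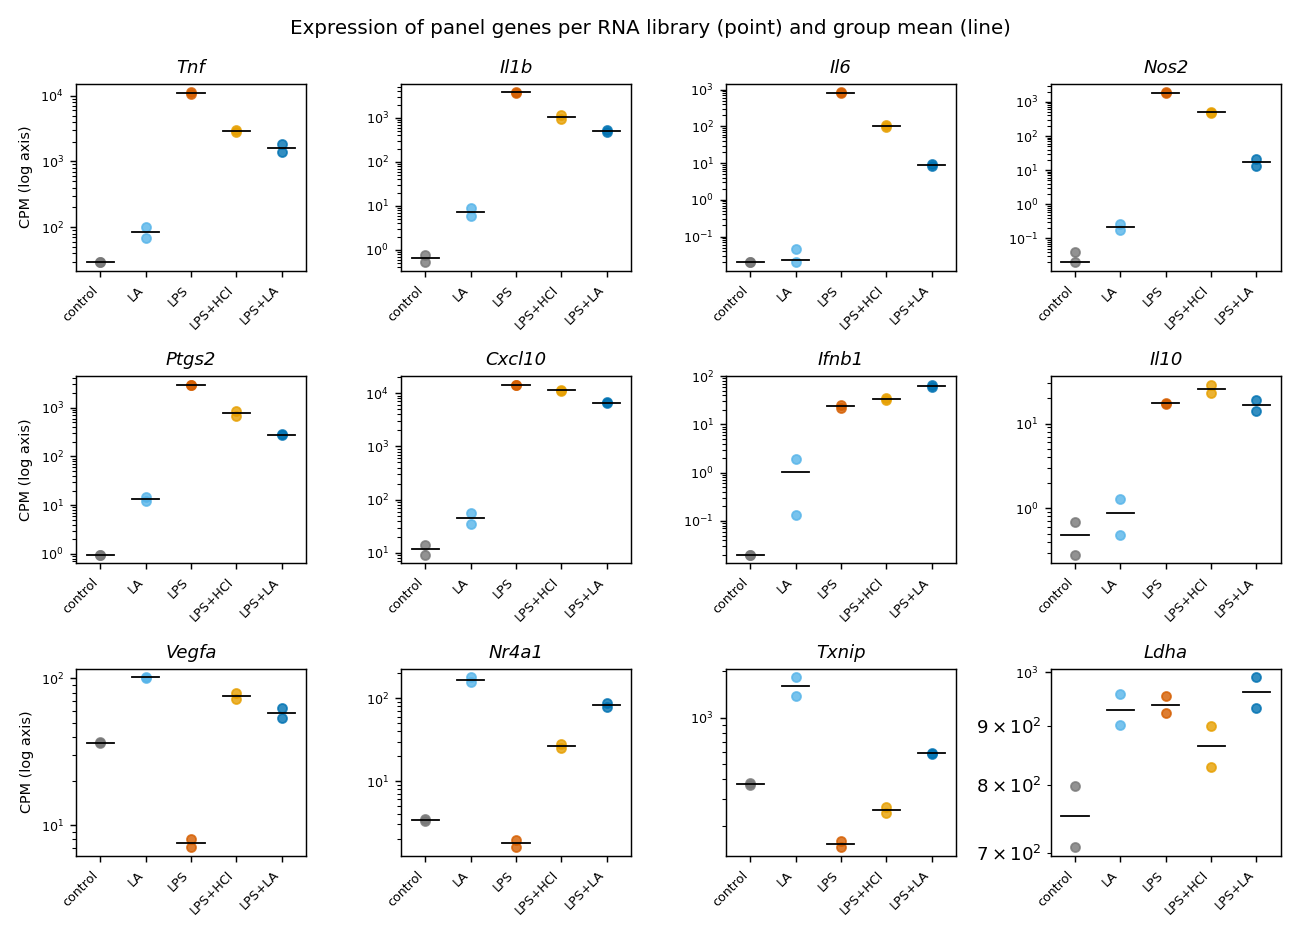
Normalised counts (CPM) on a logarithmic axis for 12 genes, with 1 point per RNA library and a line at the mean of the 2 libraries of each group; counts of 0 are drawn at the bottom of the axis. Il6 stood at 828 CPM with LPS, 104 with LPS+HCl and 8.98 with LPS+LA, while Nr4a1 stood at 1.76, 26.4 and 83.0.

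The second comparison asked what LA did without LPS. LA alone raised most members of the immediate early and cAMP target lists and 9 of 19 tested cytokines. Nr4a1 rose from 3.38 ± 0.0762 to 168 ± 16.9 CPM (log2 5.64, SE 0.13, adjusted p = 8.17e-20 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fosb, an AP-1 subunit, rose from 1.57 ± 0.447 to 67.8 ± 8.04 CPM (log2 5.43). Txnip rose from 373 ± 5.93 to 1604 ± 316 CPM and Vegfa from 36.5 ± 0.589 to 102 ± 0.61 CPM (log2 2.10 and 1.48). The greatest falls were smaller than the rises: Lpar5 (39.6 to 9.9 CPM, log2 −2.00), a lysophosphatidic acid receptor, Tlr7 (137 to 35.6 CPM, log2 −1.94), an RNA-sensing Toll-like receptor, Ptafr (123 to 33.5 CPM, log2 −1.87), the platelet-activating factor receptor, Tfap4 (11.6 to 3.24 CPM, log2 −1.85) and P2ry13 (17.1 to 4.92 CPM, log2 −1.80), a nucleotide receptor.

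Several inflammatory genes rose with LA alone to levels far below those of LPS. Tnf (29.4 to 84.9 CPM, log2 1.53), Il1b (0.644 to 7.36 CPM, log2 3.50), Ptgs2 (0.966 to 13.6 CPM, log2 3.81) and Cxcl10 (11.7 to 45.5 CPM, log2 1.95) rose, with a largest adjusted p of 0.00337 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tnf no longer passed edgeR's quasi-likelihood test when both libraries with brain transcripts were left out (log2 1.53, Benjamini-Hochberg adjusted p = 0.0705, range over its alternatives 4.34e-11 to 0.0705). Ldha rose by log2 0.30. Il12b had 16 counts with LA and 1 in control, a ratio of 17.6 (95% counting interval 2.73 to 738). It passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0264) but not without control replicate 1, control replicate 2, LA replicate 1 or both libraries with brain transcripts (adjusted p = 0.0932, 0.182, 0.404 and 0.0912, range over its alternatives 0.000221 to 0.404). Myc rose (log2 0.43), but did not pass without control replicate 1 (0.36), LA replicate 2 (0.29) or both libraries with brain transcripts (0.36).

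Nos2, Il6, Il10, Ifnb1, Ccl2, Acod1 and Slc16a3 did not pass the test with LA alone, but all except Il6 passed in some alternative. Acod1 stood at 15.9 ± 0.792 and 12.8 ± 7.97 CPM, with a log2 of −0.32 that became −1.16 and passed without LA replicate 2. Ccl2 (log2 −0.20) passed without control replicate 2 (−0.25) or LA replicate 2 (−0.35), with DESeq2 size factors (−0.21), in DESeq2's Wald test (−0.21), without the low-count filter (−0.21) and with total-count scaling (−0.31), and Slc16a3 (0.19) without control replicate 2 (0.34). Il10 (0.87) passed without LA replicate 1 (1.41). Ifnb1 had no count in control and 1.03 ± 1.26 CPM with LA, and passed edgeR's quasi-likelihood test without LA replicate 1 or LA replicate 2 (Benjamini-Hochberg adjusted p = 7.72e-08 and 0.0422) and DESeq2's Wald test (0.000514, range over its alternatives 7.72e-08 to 0.276). Nos2 had 10 counts against 1 and passed without LPS+LA replicate 1 or 2, libraries outside the comparison that enter the shared fit, or without the low-count filter (adjusted p = 0.00841, 0.00833 and 0.00967 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, range 0.00833 to 0.534).

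Of 20 targets of cAMP and CREB, a second-messenger pathway, 16 rose and 1 fell with LA alone (17 higher and 1 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 7.02e-11, adjusted p = 0.024 with an estimated correlation). Besides Nr4a1 they included Thbs1 (23.6 to 243 CPM, log2 3.36), a matrix protein, and Fosl2 (35.4 to 201 CPM, log2 2.51). Of 21 immediate early and AP-1 genes, 18 rose and 2 fell (18 higher and 2 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 2.27e-08, adjusted p = 0.0659 with an estimated correlation), with Junb (89.3 to 454 CPM, log2 2.35) and Fos (42.9 to 225 CPM, log2 2.39). Of 28 NF-kB signalling and feedback genes, 21 rose and 3 fell, against 16 and 6 with total-count scaling (21 higher and 3 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 1.67e-06, adjusted p = 0.123 with an estimated correlation). Among the risers were Zfp36 (102 to 489 CPM, log2 2.26), which destabilises cytokine messenger RNA, Dusp1 (24.1 to 88.6 CPM, log2 1.88), a kinase phosphatase, Socs3 (6.96 to 25.1 CPM, log2 1.85) and Bcl3 (22.5 to 95.2 CPM, log2 2.08). Of 19 inflammatory cytokines, 9 rose and none fell (9 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.000165, adjusted p = 0.224 with an estimated correlation), among them Osm (5.17 to 21 CPM, log2 2.02) and Csf1 (18.4 to 36 CPM, log2 0.97). Of 20 antigen presentation and costimulation genes, 18 rose and 1 fell (18 higher and 1 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 4.52e-08, adjusted p = 0.123 with an estimated correlation), by modest amounts as in H2-K1 (576 to 830.1 CPM, log2 0.53), a class I antigen-presenting molecule. In contrast, type I interferon response genes did not pass as a list, with 1 higher and 8 lower of 33 (camera with Benjamini-Hochberg adjusted p = 0.0757), and their median was −0.17 log2 while their mean was 0.05. Chemokines had 3 higher and 1 lower of 16 and did not pass (camera, Benjamini-Hochberg adjusted p = 0.388).

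Heat shock genes rose unevenly between the LA libraries. Of 14 heat shock genes, 9 rose and none fell (11 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.000221, adjusted p = 0.224 with an estimated correlation), including Bag3 (95.3 to 207 CPM, log2 1.12), a chaperone partner. Hspa1a, an inducible chaperone, stood at 306 ± 246 CPM with LA against 1.45 ± 0.106 in control, and its near-identical paralog Hspa1b at 186 ± 136 against 2.19 ± 0.0729 CPM. How reads were divided between the paralogs is uncertain. Hspb1, a small heat shock protein, had 571 counts with LA and 1 in control, a ratio of 628 with a 95% counting interval of 112 to 24853. These 3 genes passed edgeR's quasi-likelihood test with a largest Benjamini-Hochberg adjusted p of 0.00303, but a fit of the 4 compared libraries alone gave 0.0594, 0.0591 and 0.0541, and one without both libraries with brain transcripts 0.0527, 0.0519 and 0.073, the last being the highest over all alternatives. Without LA replicate 1 or 2 the log2 of Hspa1a was 8.36 or 6.50, that of Hspa1b 7.00 or 5.35 and that of Hspb1 9.55 or 7.72. Hspb1 stood at 8.09 without control replicate 1 and 10.94 without control replicate 2.

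Across all genes, edgeR's quasi-likelihood test called 4677 between LA and control, 2488 higher and 2189 lower, of which 347 and 258 changed by log2 of at least 1. Total-count scaling, with a median shift of −0.10 log2, gave 1719 higher and 3070 lower, and leaving out both libraries with brain transcripts gave 3173 calls.

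The third comparison asked how LA changed the response to LPS. LA lowered most of the inflammatory output. Il6 fell from 828 ± 38.3 CPM with LPS to 8.98 ± 0.927 with LPS+LA (log2 −6.53, SE 0.11), and Nos2 from 1884 ± 73.6 to 17.2 ± 5.89 CPM (log2 −6.78, SE 0.17). Tnf fell from 10969.7 ± 523 to 1628 ± 335 CPM (log2 −2.75) and Il1b from 3793 ± 61.5 to 501 ± 33.6 CPM (log2 −2.92). The largest adjusted p of these 4 genes was 6.07e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Il12b (735 to 22 CPM, log2 −5.06), Ptgs2 (2963 to 279.7 CPM, log2 −3.41), Acod1 (12191 to 3608 CPM, log2 −1.76), Cxcl10 (14439 to 6683 CPM, log2 −1.11) and Ccl2 (2425 to 1306 CPM, log2 −0.89) fell as well.

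The greatest falls with LA took genes back to near silence. Ccl17, a chemokine for T cells, went from 32.2 ± 4.64 CPM to 3 counts over both LPS+LA libraries, a count ratio of 0.00247 (95% counting interval 0.000508 to 0.00724). Edn1 (259.7 to 0.768 CPM, log2 −8.39), the vasoconstrictor endothelin, Serpina3g (149 to 0.714 CPM, log2 −7.68), a protease inhibitor, Csf2 (46.2 to 0.292 CPM, log2 −7.28) and Lad1 (46.2 to 0.397 CPM, log2 −6.84) followed. The greatest rises were those of Fosb (0.132 to 21.7 CPM, log2 7.31), Nr4a1 (1.76 to 83 CPM, log2 5.55), Zfp395 (0.525 to 22.8 CPM, log2 5.43), Hspb1 (0.85 to 36.7 CPM, log2 5.42) and Lyl1 (1.7 to 66.8 CPM, log2 5.29). Without LPS replicate 1 or 2 the log2 of Fosb was 6.34 or 11.80, and without LPS+LA replicate 2 that of Serpina3g was −8.61. The fitted log2 of Ccl17, −8.55, was −12.34 without LPS+LA replicate 1 and −7.60 without replicate 2. Vegfa rose from 7.59 ± 0.727 to 58.1 ± 6.63 CPM and Txnip from 153 ± 9.81 to 588 ± 7.32 CPM. Il10 stood at 17.3 ± 0.333 and 16.5 ± 3.57 CPM, and neither it nor Ldha nor Myc passed the test. Myc passed without LPS+LA replicate 2, with a log2 of −0.40 against −0.22, and Ldha with total-count scaling (0.44 against 0.03).

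Ifnb1 was called higher, at 23.8 ± 2.32 CPM with LPS and 63 ± 5.18 with LPS+LA (log2 1.40, SE 0.36, Benjamini-Hochberg adjusted p = 0.0219 in edgeR's quasi-likelihood test, range over its alternatives 8.65e-11 to 0.279). The call was lost without either LPS library, either LPS+LA library or either LPS+HCl library (adjusted p between 0.0581 and 0.149 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with a replicate block (0.0521), without both libraries with brain transcripts (0.0573) and in DESeq2's Wald test (0.279), while its log2 stayed between 1.32 and 1.51. Slc16a3 fell by log2 −0.26, which turned to 0.14 with total-count scaling. Its call was lost without LPS replicate 1, LPS replicate 2 or LPS+LA replicate 2 (log2 −0.25, −0.25 and −0.20).

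Immune families fell together with LA. Of 33 type I interferon response genes, 32 fell and 1 rose (1 higher and 32 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 3.63e-13, adjusted p = 0.312 with an estimated correlation), with Usp18 (673 to 76.6 CPM, log2 −3.14), Ifih1 (1426 to 263 CPM, log2 −2.44) and Irgm1 (1137 to 195 CPM, log2 −2.54), an immunity-related GTPase. The 16 chemokines all fell (0 higher and 16 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 1.83e-06, adjusted p = 0.136 with an estimated correlation), among them Cxcl9 (504 to 7.03 CPM, log2 −6.16) and Cxcl1 (490.5 to 42.7 CPM, log2 −3.52), a neutrophil chemokine. Of 19 inflammatory cytokines, 15 fell and 2 rose (2 higher and 15 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 2.38e-05, adjusted p = 0.312 with an estimated correlation), with Tnfsf15 (362 to 14.8 CPM, log2 −4.61), Il15 (393 to 49.6 CPM, log2 −2.99) and Csf1 (1244 to 229 CPM, log2 −2.44). The risers were Ifnb1 and Tnfsf9, a costimulatory ligand, which went from 205 ± 4.01 to 1048 ± 76.3 CPM. Of 28 NF-kB signalling and feedback genes, 25 fell and 2 rose (2 higher and 25 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 2.78e-07, adjusted p = 0.136 with an estimated correlation), including Traf1 (720.3 to 138 CPM, log2 −2.38), an adaptor, and the transcription factor subunits Nfkb1 (1152 to 341 CPM, log2 −1.75) and Nfkb2 (928 to 246 CPM, log2 −1.92). Of 21 antimicrobial and prostanoid effectors, 16 fell and 1 rose (1 higher and 16 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 1.26e-05, adjusted p = 0.111 with an estimated correlation), with Saa3 (281 to 3.27 CPM, log2 −6.43) and Casp4 (202 to 38.8 CPM, log2 −2.38), an inflammatory caspase. Of 20 antigen presentation and costimulation genes, 14 fell and 2 rose, against 11 and 7 with total-count scaling (2 higher and 14 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.000619, adjusted p = 0.312 with an estimated correlation), with Cd40 (869 to 61.6 CPM, log2 −3.82) and Cd274 (1132 to 196 CPM, log2 −2.53), an inhibitory ligand for T cells. Cell cycle genes rose, 21 of 27 with none lower (21 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 5.68e-07, adjusted p = 0.294 with an estimated correlation), such as Ccnd1 (106 to 386 CPM, log2 1.87), Cdc20 (31.6 to 77.8 CPM, log2 1.30) and Plk1 (68.1 to 137 CPM, log2 1.01), a mitotic kinase.

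**Figure D2:**
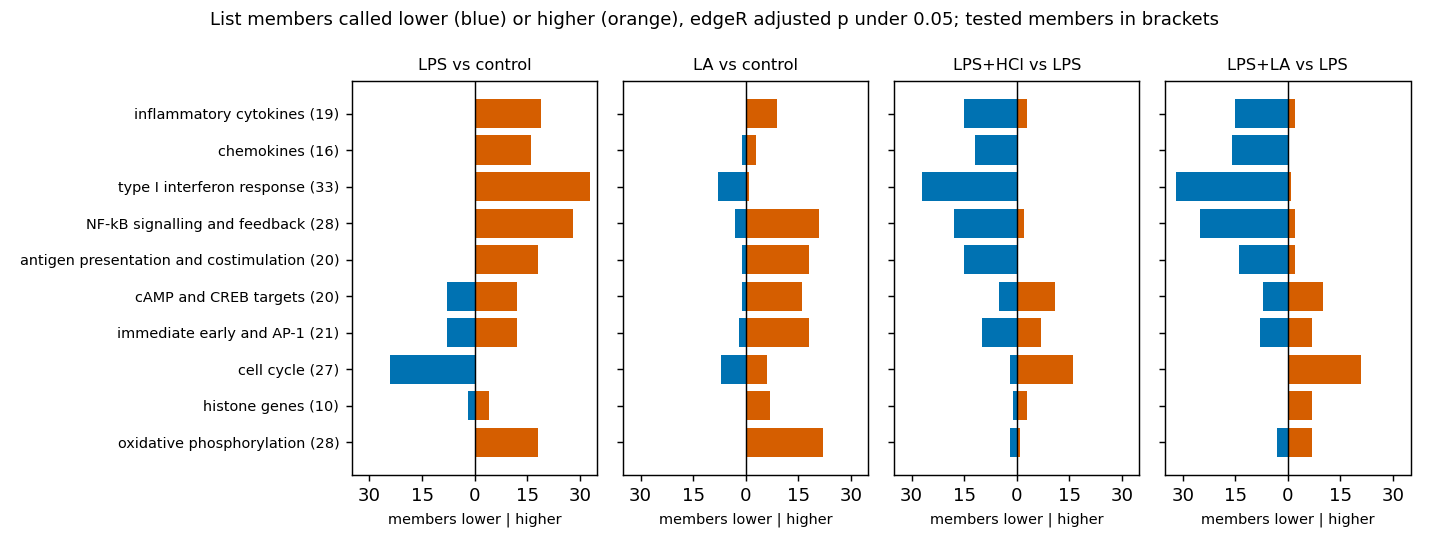
Number of members of 10 gene lists that edgeR's quasi-likelihood test called lower (bars to the left, blue) or higher (bars to the right, orange) in 4 comparisons, with the number of tested members in brackets. Of 33 type I interferon response genes, 33 were higher with LPS and 32 were lower with LPS+LA than with LPS; the oxidative phosphorylation bar of LPS against control turns to 1 higher and 26 lower with total-count scaling.

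The fall covered most of the genes that LPS had induced. Of the 1792 genes that LPS raised by log2 of at least 1, LA lowered 1533 (85.5%) and raised 66. Of the 1968 that LPS lowered as much, LA raised 1493 (75.9%) and lowered 5 further. Because the LPS libraries enter both comparisons, unchanged groups were simulated against them, and in 20 simulations at most 0.108% of induced genes were called lower. LPS still acted in the presence of LA: 1247 of the 1792 genes were called higher in LPS+LA than in LA alone. The difference between the LPS effects with and without LA was itself called for 1467 of them as smaller and for 9 as larger. The simulations gave 0 and 0, with the same limit.

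Over all genes, edgeR's quasi-likelihood test called 7191 between LPS+LA and LPS, 3569 higher and 3622 lower, of which 1367 and 1325 changed by log2 of at least 1. Total-count scaling, with a median shift of 0.40 log2, gave 6208 higher and 2032 lower.

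The interaction asked whether LA acted differently with and without LPS. For 5 panel genes LA had opposite called effects. Ptgs2 rose with LA alone and fell with LA under LPS (interaction log2 −7.21, SE 0.20), as did Il1b (−6.42), Tnf (−4.28) and Cxcl10 (−3.06), and Il12b, whose call with LA alone was fragile as given above. The largest adjusted p of the first 4 interactions was 0.00101 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The largest negative interactions belonged to genes with at most 3 counts over both control libraries, so their fitted values are no bound. These were Nos2, Edn1 and Il1a, which stood at 0.222, 0.133 and 1.04 CPM with LA alone, and Ccl17 and Csf2 at 0.0659 and 0.0223 CPM. The calls of Ccl17 without LA replicate 1 and of Csf2 and Il6 without LA replicate 2 were lost, with fitted log2 values of −8.55, −7.28 and −6.53 against −12.08, −9.46 and −8.70. Those of Nos2 (−9.88 in the full fit) and Il1a were −9.07 and −8.11 without control replicate 1, and −11.92 and −11.85 without control replicate 2. The interactions of Ccl2 (−0.69) and Myc (−0.65) were not called with total-count scaling (−0.18 and −0.14).

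The largest positive interactions came from genes that were low with LPS and higher with LPS+LA. Lyl1 stood at 110.2 ± 6.12 CPM in control, 95.9 ± 10.1 with LA, 1.7 ± 0.254 with LPS and 66.8 ± 2.29 with LPS+LA (interaction log2 5.49). Zfp395 (4.96), Cd300lb (4.75) and S1pr1 (4.47), a sphingosine phosphate receptor of cell trafficking, had the same order of groups under LPS. Lpar5 fell with LA alone and rose with it under LPS (5.29), at 1.02 ± 0.338 CPM with LPS and 10 ± 0.225 with LPS+LA. Vegfa had an interaction of 1.46, while those of Nr4a1, Txnip, Il10, Ifnb1 and Acod1 did not pass the test. For Acod1 (−1.44) the interaction passed without LA replicate 1 (−1.97) or LA replicate 2 (−0.60), and for Ifnb1 (−5.95) and Il10 (−0.93) without LA replicate 1 (−6.83 and −1.48). Acod1 and Ifnb1 also passed in DESeq2's Wald test (−1.47 and −5.73). That of Txnip (−0.16) flipped to 0.35 with total-count scaling and passed there, and it passed at −0.35 without LA replicate 2.

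By list, the interaction was lower for all 28 NF-kB signalling and feedback genes (0 higher and 28 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 1.44e-14, adjusted p = 0.0448 with an estimated correlation), as for Zfp36 (−2.60), Traf1 (−2.83), Socs3 (−2.44). It was lower for 31 of 33 type I interferon response genes and higher for none (0 higher and 32 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 2.8e-14, adjusted p = 0.255 with an estimated correlation), as for Ifih1 (−2.30), Usp18 (−2.97), Ddx58 (−1.91). Inflammatory cytokines had 14 lower and 1 higher (1 higher and 14 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 3e-08, adjusted p = 0.133 with an estimated correlation), the latter being Tnfsf9 (2.28), and chemokines had 14 lower and none higher (0 higher and 15 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 2.25e-07, adjusted p = 0.0948 with an estimated correlation). For antimicrobial effectors 16 were lower and none higher (0 higher and 17 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 3e-08, adjusted p = 0.043 with an estimated correlation), and for antigen presentation 17 were lower and none higher, against 14 lower and 2 higher with total-count scaling (0 higher and 17 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 2.94e-08, adjusted p = 0.133 with an estimated correlation). Immediate early genes went both ways, with 14 lower and 5 higher (5 higher and 14 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.00298, adjusted p = 0.154 with an estimated correlation), as for Junb (−2.58), Klf2 (3.10). For cAMP and CREB targets 11 were lower and 4 higher (4 higher and 11 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.00626, adjusted p = 0.133 with an estimated correlation), with Nr4a3 (−6.13), Pde4b (−2.76), Plaur (−2.66), where Nr4a3 stood at −7.04 without control replicate 1. Cell cycle genes had 23 higher and none lower (23 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 3e-08, adjusted p = 0.133 with an estimated correlation). For oxidative phosphorylation 13 were lower and none higher, a direction that flipped to 1 lower and 10 higher with total-count scaling (0 higher and 13 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.00359, adjusted p = 0.419 with an estimated correlation). In all, 5409 interactions were called, 2492 higher and 2917 lower, against 5917 and 1294 with total-count scaling, whose median shift was 0.51 log2.

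LPS+HCl was compared with LPS to ask what acidity without added lactate did. HCl moved many of the same genes in the same direction by smaller amounts. Il6 fell from 828 ± 38.3 to 104 ± 9.97 CPM (log2 −2.99, SE 0.09), Nos2 to 495 ± 14.6 (log2 −1.93), Tnf to 2878 ± 125 (log2 −1.93) and Il1b to 1043 ± 135 CPM (log2 −1.86). The largest adjusted p of these 4 genes was 0.000576 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Il12b (735 to 70.5 CPM, log2 −3.38), Ptgs2 (2963 to 767 CPM, log2 −1.95) and Ccl2 (2425 to 1499 CPM, log2 −0.69) fell, as did Myc (log2 −0.67). The greatest falls were those of Csf2 (46.2 to 1.28 CPM, log2 −5.17), Ccl17 (32.2 to 1.11 CPM, log2 −4.85), Lad1 (46.2 to 2.02 CPM, log2 −4.51), Sele (28.7 to 1.44 CPM, log2 −4.31), an endothelial-type adhesion molecule, and Edn1 (259.7 to 19.9 CPM, log2 −3.71). The greatest rises were those of Nr4a1 (1.76 to 26.4 CPM, log2 3.90), Fbxo40 (2.52 to 31 CPM, log2 3.62), Vegfa (7.59 to 76.1 CPM, log2 3.33), S1pr1 (3.67 to 36.7 CPM, log2 3.32) and Plekhg3 (2.42 to 24.1 CPM, log2 3.31). Txnip rose too (log2 0.73).

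Cxcl10, Acod1 and Ifnb1 did not pass the test with HCl, at 11289 ± 479, 8511 ± 34 and 33.6 ± 1.19 CPM, but each passed without LA replicate 1 or LA replicate 2, at log2 values of −0.36, −0.52 and 0.50 without the former, and in a fit of only the libraries compared (−0.33, −0.50 and 0.52). Il10 was called higher (log2 0.57), a call lost without LPS replicate 1, LPS replicate 2 or LPS+HCl replicate 2 (log2 0.55, 0.59 and 0.39), without both libraries with brain transcripts (0.39) or in DESeq2's Wald test (0.56). Slc16a3 was called lower (log2 −0.27), lost without LPS replicate 1, LPS replicate 2 or LPS+HCl replicate 1 (−0.28, −0.28 and −0.23) or with total-count scaling (−0.04). Ldha did not pass.

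By list, 27 of 33 type I interferon response genes fell with HCl and none rose (0 higher and 29 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 1.3e-08, adjusted p = 0.421 with an estimated correlation), such as Gbp3 (632 to 264 CPM, log2 −1.26) and Usp18 (673 to 325 CPM, log2 −1.05). Of 19 inflammatory cytokines, 15 fell and 3 rose (3 higher and 15 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 2.12e-05, adjusted p = 0.274 with an estimated correlation), with Tnfsf15 (362 to 50.7 CPM, log2 −2.83). Of 16 chemokines, 12 fell and none rose (0 higher and 12 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 2.18e-05, adjusted p = 0.244 with an estimated correlation), including Cxcl9 (504 to 80.8 CPM, log2 −2.64) and Cxcl1 (490.5 to 64.3 CPM, log2 −2.93). Antimicrobial effectors had 14 lower and 2 higher (2 higher and 14 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.000162, adjusted p = 0.201 with an estimated correlation). In that list Saa3 (281 to 49.6 CPM, log2 −2.50) and Nlrp3 (956 to 424 CPM, log2 −1.17), an inflammasome sensor, fell and Cd14 (2538 to 4937 CPM, log2 0.96), the LPS co-receptor, rose. Antigen presentation genes had 15 lower and none higher, against 9 and 2 with total-count scaling (0 higher and 15 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 7.42e-05, adjusted p = 0.274 with an estimated correlation), as for Cd40 (869 to 309 CPM, log2 −1.49). NF-kB signalling and feedback genes had 18 lower and 2 higher, against 12 and 9 with total-count scaling (2 higher and 18 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.000162, adjusted p = 0.274 with an estimated correlation), with Traf1 (720.3 to 347 CPM, log2 −1.05) lower and Dusp1 (349 to 742 CPM, log2 1.09) higher. Of 27 cell cycle genes, 16 rose and 2 fell (17 higher and 2 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.000162, adjusted p = 0.322 with an estimated correlation), with Ccnd1 (106 to 243 CPM, log2 1.20). LPS+HCl replicate 2 held the brain transcripts given above.

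Across all genes, edgeR's quasi-likelihood test called 4742 between LPS+HCl and LPS, 2201 higher and 2541 lower, of which 702 and 405 changed by log2 of at least 1. Total-count scaling, with a median shift of 0.24 log2, gave 4535 higher and 1310 lower, and leaving out both libraries with brain transcripts gave 3587 calls. HCl lowered 1146 (64.0%) of the 1792 LPS-induced genes and raised 131, and it raised 989 (50.3%) of the 1968 that LPS lowered and lowered 40 further.

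The LA and HCl effects under LPS were then set side by side. Across 12213 genes, which are not independent replicates, the log2 values of both comparisons correlated at 0.596 (Spearman 0.747), while groups simulated without any effect but sharing the LPS libraries gave a mean of 0.532 and at most 0.575. The covariance was 0.839 against a simulated 0.0988, a difference of 0.740. Both acids lowered 2232 genes and raised 1792, where independent lists would share 753.6 and 643.2, and 96 genes went opposite ways. In the simulations, where no acid effect leaves few calls to share, at most 0 and 1 genes were shared. On log CPM differences the correlation was 0.722 with both LPS libraries shared, and 0.648 or 0.647 with a different LPS library for each comparison. Shared calls were not retested with 1 LPS library each, so part of their excess may come from the shared libraries. Over the 7813 genes called in either comparison the median absolute log2 was 0.73 for LA and 0.41 for HCl.

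**Figure D3:**
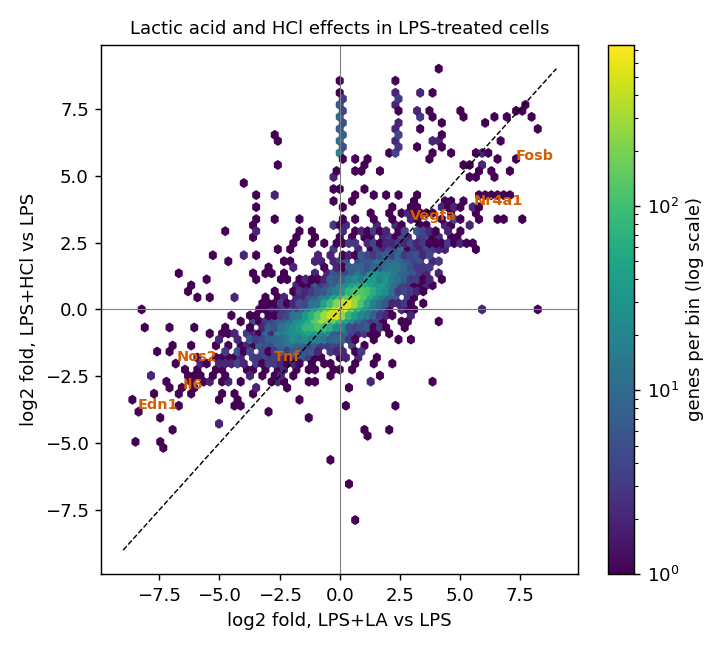
Log2 fold change of LPS+LA against LPS (horizontal axis) and of LPS+HCl against LPS (vertical axis) for 12213 genes binned in hexagons, with colour for genes per bin on a logarithmic scale and a dashed line of equality. Il6, at −6.53 with LA and −2.99 with HCl, and Nos2, at −6.78 and −1.93, lie above the line, with larger falls with LA.

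The direct comparison of LPS+LA with LPS+HCl asked where the LA and HCl groups differed. Their acidity is not known to match, since the pH of LPS+LA is not stated. LPS+LA held much less of several inflammatory transcripts. Nos2 was at 17.2 ± 5.89 against 495 ± 14.6 CPM (log2 −4.85, SE 0.16) and Il6 at 8.98 ± 0.927 against 104 ± 9.97 CPM (log2 −3.54, SE 0.11), with adjusted p of 1.22e-09 and 5.49e-16 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Edn1 (19.9 to 0.768 CPM, log2 −4.68), Serpina3g (17.6 to 0.714 CPM, log2 −4.61), Col27a1 (10.1 to 0.585 CPM, log2 −4.10), a collagen, and Zfp811 (13.1 to 0.768 CPM, log2 −4.08) had the other greatest differences downward. Il12b (70.5 to 22 CPM, log2 −1.68), Ptgs2 (767 to 279.7 CPM, log2 −1.46) and Il1b (1043 to 501 CPM, log2 −1.06) were lower as well. Higher with LA were Lyl1 (9.34 to 66.8 CPM, log2 2.84), Lpin1 (2.99 to 20.3 CPM, log2 2.76), a phosphatidate phosphatase, Slc26a11 (3.02 to 20.1 CPM, log2 2.73), an anion transporter, Sesn1 (6.41 to 40.7 CPM, log2 2.67), a stress-response protein, Nr4a1 (26.4 to 83 CPM, log2 1.65) and Txnip (254 to 588 CPM, log2 1.21). Hspb1 was also called higher (log2 2.90), but not without LPS+HCl replicate 1 (3.00) or replicate 2 (2.81), and without LPS+LA replicate 2 the log2 of Serpina3g was −5.53.

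Some calls between LPS+LA and LPS+HCl were lost with a library left out, at log2 values close to the full fit for Tnf, Acod1 and Cxcl10. Those of Tnf (log2 −0.82) and Acod1 (−1.24) were lost without either LPS+HCl library, and that of Acod1 also without either LPS+LA library (Tnf −0.86 and −0.78, Acod1 −1.25 to −1.21). Those of Cxcl10 (−0.76) and Ccl2 (−0.20) were lost without any 1 library of LPS, LPS+LA or LPS+HCl (Cxcl10 −0.80 to −0.71, Ccl2 −0.21 to −0.17). Il10 (−0.64) was lost without LPS+LA replicate 1 (−0.42) or LPS+HCl replicate 2 (−0.46). Myc (0.45) was lost without LPS+LA replicate 2 (0.28) or LPS+HCl replicate 1 (0.34), and Vegfa (−0.39) without LPS+LA replicate 1 (−0.26). With total-count scaling Cxcl10, Ccl2, Il10 and Vegfa did not pass either, nor did Hspb1, Tnf, Acod1, Cxcl10, Ccl2 and Il10 without both libraries with brain transcripts or Cxcl10 without the low-count filter. Ifnb1, Slc16a3 and Ldha did not pass, although Ifnb1 did without LA replicate 1 or LA replicate 2 (log2 0.91 without the former), Ldha with total-count scaling (0.32) and both in a fit of only the libraries compared (0.91 and 0.15).

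Of 33 type I interferon response genes, 32 were lower with LPS+LA than with LPS+HCl and none higher (1 higher and 32 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 7.93e-16, adjusted p = 0.295 with an estimated correlation), with Ifih1 (−1.65), Usp18 (−2.09), Igtp (−2.18). NF-kB signalling and feedback genes had 23 lower and 2 higher (2 higher and 23 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 4.65e-07, adjusted p = 0.217 with an estimated correlation), with Socs1 (−2.09), Tnip3 (−1.49). Antimicrobial effectors had 16 lower and none higher (0 higher and 16 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 1.36e-06, adjusted p = 0.0733 with an estimated correlation), with Saa3 (49.6 to 3.27 CPM, log2 −3.92). Chemokines had 13 lower and none higher (0 higher and 13 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.000226, adjusted p = 0.217 with an estimated correlation), and cytokines 14 lower and 2 higher (2 higher and 14 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.000322, adjusted p = 0.358 with an estimated correlation), with Cxcl9 (−3.52), Il1rn (−2.79), Il1a (−2.60). Antigen presentation genes had 9 lower and 2 higher, against 7 and 4 with total-count scaling (3 higher and 9 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.0303, adjusted p = 0.533 with an estimated correlation). Cell cycle genes had 21 higher and none lower (21 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 3.96e-07, adjusted p = 0.217 with an estimated correlation), as for Mcm3 (0.70), Cdc6 (1.67).

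Among the 3622 genes that LA lowered under LPS, 2267 were called lower than with HCl and 55 higher, against at most 1 and 2 in 20 simulations in which both acids had the LPS+LA mean. Over all genes, edgeR's quasi-likelihood test called 4996 between LPS+LA and LPS+HCl, 2243 higher and 2753 lower, of which 466 and 741 changed by log2 of at least 1. Total-count scaling, with a median shift of 0.17 log2, gave 3947 higher and 1893 lower, and leaving out both libraries with brain transcripts gave 3485 calls.

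ATAC-seq asked whether chromatin accessibility followed. Some sites gained with LPS had no peak with LPS+LA, and others kept one. Merging the peaks of all 12 samples gave 127890 sites, of which 56120 had a peak in every sample. LPS samples had 94629 ± 5933 peaks and LPS+LA samples 94807 ± 7999, against 84496 ± 3560 in control and 78813 ± 2073 in LA (mean ± SD, n = 3). Samples treated with LPS had 13063 more peaks on average within the same LA state (two-sided exact permutation test, p = 0.005, 400 arrangements). With only peaks above the pooled median score of 28.2 the difference was 5972 (exact permutation test, p = 0.07). The LA difference of −2752 peaks did not pass (two-sided exact permutation test, p = 0.39). Peak sets overlapped more within groups than between them, with a mean Jaccard index of base pairs of 0.767 and 0.666 (exact permutation test, p = 6.49e-05, the smallest that the 15400 partitions can give).

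Of 19 panel genes, 8 had a site gained with LPS within 10 kb of their bounds. Tnf, Il1b, Il12b and Ifnb1 had none, and inflammatory genes were not tested against others. A site gained with LPS lay just outside Il6, at chromosome 5, 30020388 to 30021082 (GRCm38), 413 bp from the gene bounds. It had a peak in 3 of 3 LPS samples and in 0 of 3 samples of control, LA and LPS+LA. The same pattern held 60 bp outside Ptgs2 (chromosome 1, 150108294 to 150109047), 753 bp outside Nos2 (chromosome 11, 78919749 to 78920034), 1548 bp outside Ccl2 (chromosome 11, 82039000 to 82039347) and 6088 bp outside Arg1 (chromosome 10, 24908834 to 24909119), the arginase gene. Other LPS-opened sites had a peak in 3 of 3 LPS+LA samples: at Cxcl10 (chromosome 5, 92345674 to 92346669, overlapping the gene bounds), 216 bp outside Acod1 (chromosome 14, 103056789 to 103057251), 4094 bp outside Il10 (chromosome 1, 131015273 to 131015751), 4057 bp outside Arg1 (24931527 to 24931867, also in 3 of 3 LA samples) and inside Nos2 (78950259 to 78950738). Sites present in 3 of 3 LPS+LA and 0 of 3 LPS samples lay inside Il12b (chromosome 11, 44410550 to 44410844), inside Nos2 (78935210 to 78935572 and 78956340 to 78956764), 3046 bp outside Il10 (131028016 to 131028268), 1193 bp outside Cxcl10 (chromosome 5, 92345122 to 92345445) and 4187 bp outside Txnip (chromosome 3, 96553508 to 96553770). Sites found only in the 3 control samples lay inside Tnf (chromosome 17, 35201022 to 35201282), across the edge of Il10 (131019477 to 131020025), 5583 bp outside Nr4a1 (chromosome 15, 101247972 to 101248319) and 3623 bp outside Myc (chromosome 15, 61993984 to 61994261). The gene table used here gives bounds without exons or strand.

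**Figure D4:**
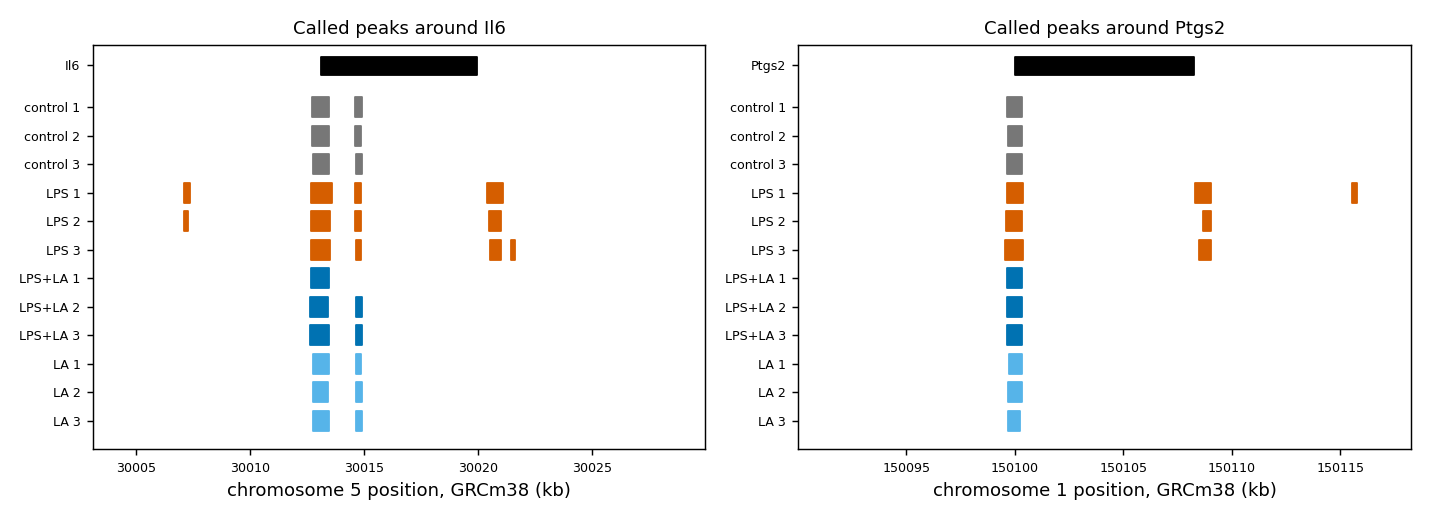
Called peaks (coloured bars) in each of the 12 ATAC samples within 10 kb of Il6 and of Ptgs2, with the gene bounds in black and GRCm38 position in kb on the horizontal axis. The sites at 30020388 on chromosome 5 and at 150108294 on chromosome 1 have a peak in the 3 LPS samples only.

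Genome-wide, 10579 sites had a peak in 3 of 3 LPS samples and 0 of 3 controls, and 3125 the reverse. With the 76680 top-scoring peaks of each sample the counts were 7867 and 5519, and without LPS replicate 1 the lost sites numbered 4852. Of the 10579 LPS-gained sites, 5798 (54.8%) kept a peak in 3 of 3 LPS+LA samples and 2083 (19.7%) in none. On average 68.3% were present in an LPS+LA sample and 17.02% in an LA sample. Sites defined on only 2 LPS samples were found in 95.7%, 89.9% or 76.3% of cases in the LPS sample left out, and on average in 67.0%, 65.6% or 61.8% of cases in LPS+LA samples. Of the 3125 LPS-lost sites, 1862 (59.6%) had no peak in LPS+LA either. LPS+LA against LA gave 7681 gained and 618 lost sites, or 4465 and 2342 with equal numbers of top peaks. Leaving out a sample relaxes the criterion, and without LPS+LA replicate 1 that comparison gave 12867 and 695, and without LPS+LA replicate 2, LPS+LA replicate 3, LA replicate 1 or LA replicate 3 the lost sites numbered 951, 1023, 1096 or 939.

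LA against control gave 1958 gained and 3040 lost sites, but with equal numbers of top peaks the direction flipped to 2528 and 1869. LPS+LA against LPS gave 2869 gained and 2932 lost sites, with 2968 and 3051 at equal numbers. Lost sites numbered 5332 without control replicate 2 and 4604 without LA replicate 2 in the first of these, and 5033 without LPS replicate 3 in the second, where 5492 were gained without LPS+LA replicate 1. Across both LA states, 3453 sites had a peak in 6 of 6 LPS-treated and 0 of 6 other samples, and 223 the reverse (2276 and 960 at equal numbers, 369 lost without LA replicate 1). Across both LPS states, 304 sites were gained in 6 of 6 LA-treated samples and 151 lost (501 and 115 at equal numbers, with 258 lost without LPS replicate 3 and 227 without control replicate 2). Control and LPS samples were sequenced in lane 5 and the LA-treated samples in lane 6, so effects of LA and lane on chromatin cannot be told apart.

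**Figure D5:**
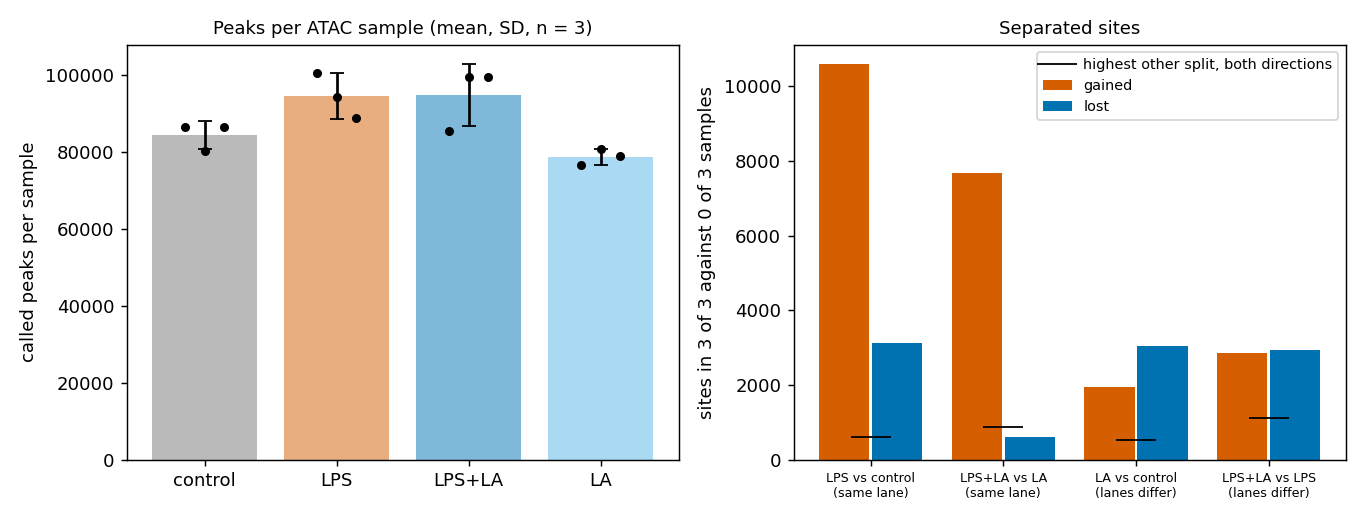
Left, called peaks per ATAC sample (points) with group mean (bar) and SD (error bar) of 3 samples, from 78813 in LA to 94807 in LPS+LA. Right, sites with a peak in 3 of 3 samples of one group and 0 of 3 of the other, gained in orange and lost in blue, with a line at the highest of the other splits, as in 10579 gained with LPS against control; for LA against control the excess of lost sites flips at equal numbers of top peaks.

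A site gained with LPS lay within 50 kb of the bounds of 2883 of 3948 genes called higher with LPS (73.0%) and of 2409 of 4268 genes not called (56.4%). The odds ratio was 2.09 (two-sided Fisher's exact test across genes, which are not independent replicates, p = 6.37e-56), and 2.07 over 5 strata of gene length. For genes called lower with LPS the odds ratio was 0.991 (Fisher's exact test, p = 0.841). Sites lost with LPS+LA lay near 34.7% of genes called lower with LPS+LA and near 23.6% of genes not called, an odds ratio of 1.71 (Fisher's exact test, p = 6.47e-29). Sites gained with LPS+LA lay near more of the genes called either way, with odds ratios of 1.30 for higher and 1.34 for lower genes.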

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

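Tests of carry-over, total-count scaling, unstimulated samples for the lane and other sample splits were chosen after the results were seen. With an interaction called in edgeR, 514 genes were called higher with LA alone and lower with it under LPS, and 371 the reverse. Of these, 36 and 24 changed by log2 of at least 1 both ways. LA raised 1279 genes and lowered 1175 both alone and under LPS. The 371 became 237 without both libraries with brain transcripts and 239 without control replicate 2. Of the panel genes, the interaction was −4.28 for Tnf, −6.42 for Il1b, −8.83 for Il12b, −3.06 for Cxcl10 and −7.21 for Ptgs2 (log2). For Il12b, with 1 control count, the fitted value is no bound and was −10.87 without control replicate 1, −8.01 without control replicate 2, −6.91 without LA replicate 1 and −9.62 without LA replicate 2.

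For the 514 genes, reads carried over from LPS libraries would raise each abundant LPS-induced gene by a like share. Of 136 such genes 63 did not rise with LA alone, and the rise of Tnf was 0.508% of its LPS rise while the highest was 42.3%, which argues against carry-over as the whole cause. A single LA library is argued against too, since at least 76.3% of the genes kept both calls without either LA library in turn. Scaling stays open. Total-count scaling shifts all genes against both calls, so the 193 (37.5%) that kept them decide nothing, and the reverse set grew to 1109. Still, 5 of 5 panel genes kept both calls. A biological reading, that LA acts differently on resting and LPS-treated cells, is a hypothesis found and tested on these data.

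The second pattern was the 2932 ATAC sites with a peak in each LPS sample and in no LPS+LA sample, which also differ by lane. Fewer called peaks are argued against, since with equal numbers of top peaks the count was 104% of the main one. The lane as a cause predicts loss in LA samples too. Of 444 such sites present in each control sample, 34.0% (95% binomial interval 29.8 to 38.5) were missing from each LA sample. The share for other sites present in each control and LPS sample was not measured, so this value does not decide. Other tests left the lane open: 71.0% had no control peak against 25.6 to 28.7% of score-matched sites, but the mirror set in LA against control, 37.2%, also lay above its matched range of 15.3 to 17.8%, so that excess does not separate lane from treatment, and the nearest genes of lost and kept sites differed by a median of −0.0532 log2 (permutation test, p = 0.234). The lane may account for part or all of the loss, and LA and lane cannot be told apart here.

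With 3 against 3 ATAC samples only the real one of 10 splits gave as many sites, and 10 are too few for a share under 0.05. Real and highest other values were 13704 and 602 for LPS and 4998 and 533 for LA against control. For LPS+LA they were 5801 and 1130 against LPS and 8299 and 873 against LA. Across all 12 samples only the real one of 100 splits drawn gave as many, a share under 0.05. These were 3676 against at most 45 for LPS and 455 against at most 46 for LA. Replicates may be technical, so chance between cultures stays open, and the LA split is also the lane split.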

How the results depend on the processing

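Tests with total-count scaling, without both libraries with brain transcripts and on log CPM differences were added after seeing the data. Of 242 alternatives of 23 main results, 229 were rated the same, counts by total, not direction. A limit of log2 at least 1 cannot raise a count, and it left 3760 genes for LPS against control, 605 for LA against control, 2692 for LPS+LA against LPS, 1107 for LPS+HCl against LPS, 1207 for LPS+LA against LPS+HCl and 2335 interactions. With an estimated correlation camera called 3 of 9 lists for LPS against control, 1 of 10 for LA against control, 2 of 10 for the interaction, and 0 of 9 for LPS+LA against LPS, 0 of 7 for LPS+HCl against LPS and 0 of 9 for LPS+LA against LPS+HCl; the cause was not tested. The LPS difference in peaks above the pooled median score was 5972 and did not pass, and the cause was not tested.

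Total-count scaling reversed 10 gene values; by construction, other library factors shift all genes of a contrast alike. In LPS against control these were Slc16a3 (−0.15), Ldha (−0.40), Atp5b (−0.18) and Atp5a1 (−0.19), and in LPS+LA against LPS Slc16a3 (0.14). Among interactions they were Slc16a3 (0.056), Ldha (0.24), Txnip (0.35), Atp5f1 (0.0030) and Sdhd (0.0021). Of the 347 gene values, DESeq2's Wald test kept 341, DESeq2 size factors 346, no filter 344, a fit of only the libraries compared 335 of 343, total-count scaling 326 and the fit without both libraries with brain transcripts 332. The latter gave 7046, 3173, 7025, 3587, 3485 and 4685 calls in the 6 contrasts in the order above. Of 3470 values with a single library left out, 54 lost and 23 gained a call. A group with 1 library left was assumed to vary like the others.

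With single libraries left out, genes called ranged from 6842 to 8089 for LPS against control, 3478 to 4786 for LA against control, 6035 to 7381 for LPS+LA against LPS, 3477 to 5066 for LPS+HCl against LPS, 3612 to 5279 for LPS+LA against LPS+HCl and 4509 to 5266 for the interaction. LPS-induced genes lowered by LA ranged from 81.2 to 86.9%. The LPS difference in peaks ranged from 11553.6 to 15372.3 and the LA difference from −4207.58 to −443. Separated sites ranged from 13704 to 17324 for LPS against control, 4997 to 7457 for LA against control, 5801 to 8596 for LPS+LA against LPS, 3771 to 4874 for LPS and 514 to 604 for LA across all samples.

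The replicate numbers did not pair the RNA libraries, with correlations of deviations of −0.05 to 0.05 between groups except −0.50 for control and LPS+HCl, which hold the libraries with brain transcripts. A replicate block gave 7849, 4663, 7141, 4688, 4912 and 5380 calls. It ended the calls of Ifnb1 and the MondoA list in LPS+LA against LPS and changed no other call of a named gene or list. For peak numbers the block gave exact p = 0.03125 for LPS and 0.5625 for LA.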

Other observations

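Tests of the brain transcripts were chosen after the result was seen. Histone genes, whose products package DNA, rose with LA. With LA alone 7 of 10 rose and none fell (10 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 2.19e-07, adjusted p = 0.123 with an estimated correlation), with Hist1h1c (17.7 to 117 CPM, log2 2.72), a linker histone, Hist1h2bc (16 to 115 CPM, log2 2.85) and H3f3b (296 to 578 CPM, log2 0.96). Under LPS 7 rose with LA (7 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.00325, adjusted p = 0.312 with an estimated correlation), and 9 were higher with LPS+LA than with LPS+HCl (9 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 8.11e-05, adjusted p = 0.217 with an estimated correlation). Genes of MondoA and glucose sensing rose with LA alone, 5 of 6 (5 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.000738, adjusted p = 0.224 with an estimated correlation), among them Arrdc4 (9.02 to 47.1 CPM, log2 2.38) and Klf10 (40.9 to 271 CPM, log2 2.73), and under LPS 4 rose (4 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.0473, adjusted p = 0.561 with an estimated correlation), a list call lost with a replicate block (adjusted p = 0.0581 in camera with Benjamini-Hochberg adjustment). Without LPS replicate 2 the log2 of Arrdc3 under LPS was 4.63 against 3.94.

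Oxidative phosphorylation genes rose modestly with LA alone, 22 of 28 with none lower (25 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 1.54e-07, adjusted p = 0.15 with an estimated correlation), as in Cox5a (72.1 to 105 CPM, log2 0.54). Of 18 NRF2 oxidative stress genes 10 rose and none fell, against 7 and 1 with total-count scaling (10 higher and 0 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.0241, adjusted p = 0.357 with an estimated correlation), such as Gclm (93.6 to 134 CPM, log2 0.52), which serves glutathione synthesis. Lysosome and TFEB target genes were higher with LPS+LA than with LPS+HCl for 14 of 32 and lower for 3, against 23 and 0 with total-count scaling (14 higher and 3 lower adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.00451, adjusted p = 0.393 with an estimated correlation). They included Tfeb (7.87 to 30.9 CPM, log2 1.97), a regulator of lysosome genes, and its partners Flcn (9.98 to 26.3 CPM, log2 1.40) and Fnip2 (32 to 119 CPM, log2 1.90).

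Other lists passed in none of the 6 contrasts (camera with Benjamini-Hochberg adjustment). Their lowest adjusted p over the contrasts was 0.0570 for the integrated stress response, 0.0579 for cholesterol synthesis, 0.0618 for lactate and proton sensing and transport, 0.102 for alternative activation, 0.139 for the unfolded protein response and 0.141 for macrophage identity. It was 0.152 for LXR targets, 0.315 for YAP and TEAD targets and 0.571 for histone acetyltransferases and deacetylases. Among marker lists of other cells it was 0.0579 for fibroblasts, 0.0699 for dendritic cells, 0.252 for neutrophils and 0.531 for T cells. Dendritic cell markers summed to 112 CPM in control, 178 in LA, 295 in LPS, 224 in LPS+HCl and 189.5 in LPS+LA, fibroblast markers to at most 15.4 CPM and neutrophil markers to at most 13.3 CPM in a group. Markers of B, natural killer, erythroid and mast cells had too few tested members, and summed to at most 4.65, 0.387, 0.767 and 2.15 CPM in a group.

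Brain transcripts stood out in control replicate 1 and LPS+HCl replicate 2. Of 30 neuron markers 27 were used, since 3 reached 5 CPM in other libraries, and astrocyte markers summed to 8.25 and 10.99 CPM in these libraries against at most 2.06 elsewhere, oligodendrocyte markers to 3.27 and 6.02 against 2.46. Markers of liver, testis, and kidney and gut were not above the other libraries, but only 4, 2 and 3 markers were used. Striated muscle stood at 2.02 and 7.13 against 5.79. A response of the cells is argued against, since the partner library of the same group held at most 17.1% of the neuron marker level. RNA from brain tissue may account for the signal, with neuron marker levels correlated at 0.848 between both libraries across markers, but how it came there was not tested.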
